A study of Mus musculus with 14 samples.

How the data were processed

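Total RNA of laser-cut SCN from wild-type and Vipr2-/- mice was sequenced in 14 libraries, in 4 groups of 2 genotypes by 2 conditions (nSVE and SVE), with 4 libraries per wild-type and 3 per Vipr2-/- group. Groups came from the sample titles, and the columns of the deposited table were joined to the samples by the codes that both carry. Per the labels' protocols, mice spent 14 days in a light-dark cycle and the exercised mice another 14 days in free run before SVE. Wild-type mice that did not entrain and arrhythmic nSVE Vipr2-/- mice were excluded by the authors. The SCN was stained with cresyl violet, cut by laser, and sequenced as paired ends from a random-primed total RNA kit. Per the submitters' processing notes, reads were trimmed with Trimmomatic, checked with FastQC, aligned with HISAT2, counted per gene with StringTie and normalized with DESeq2; no versions are given. The design text names the mouse build GRCm38 and the processing notes GRCm39. Coordinates in the table settled this in favour of GRCm38: of 55401 genes, 54349 have their versioned identifier in GENCODE M21, and each of these 54349 has that annotation's coordinates.

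The deposited values are a signal per gene and library that the authors made by dividing gene counts by 1 DESeq2 size factor per library. Whole reads were recovered from them, to within 0.001 reads for each value, as multiples of the value of 1 read, and gave the read totals per library. A second sheet that lists column names was not used. Intervals and floors cover counting error only, since the reads carry no molecular identifiers; a group at 0 was set to a floor of 3 reads over the group for a fold.

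Genes with a value of at least 10 in at least 3 libraries were tested, 18175 in all. Values were log2 transformed with a pseudocount of 1 and fitted by limma 3.58.1 (R 4.3.3) with its mean-variance trend, 1 mean per group over the 14 libraries. It used moderated tests and Benjamini-Hochberg adjustment over genes within each of 6 comparisons, with calls at an adjusted p under 0.05. The comparisons were the genotypes under nSVE, under SVE and averaged over both, SVE against nSVE in each genotype, and the interaction. In addition, 32 gene lists of SCN function and of cell types were tested with camera at a preset correlation between genes of 0.01, two-sided and adjusted over the 32 lists, and each call is given beside its value with an estimated correlation. The gene test, the filter, the lists, the rule for named genes and the alternatives listed next were chosen before the data were examined.

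The named genes are Vipr2; in each comparison, the 10 largest rises and 10 largest falls among called genes with an official symbol and a group mean of at least 50; the 5 genes with the smallest p where fewer than 5 passed; up to 4 called members of each list; and Per1, Per2, Bmal1, Nr1d1, Dbp, Vip, Avp, Prok2 and Fos whether or not they passed. Chosen after their values were seen were the list members Egr1, Cirbp, Rbm3, Gad2 and Lhx1. So were Meg3, Miat, Snhg11, Shank1, Shank2, Maob, Ddc (in the averaged comparison), Tmem51 (between the genotypes), Rgs16 and Cry1 (with SVE in Vipr2-/- mice), Nnat, Dlk1, Mirg, Chga, Tmem121, Gm20658, D430020J02Rik and Gm1848. A few genes that these rules select are not reported here.

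Alternatives were pseudocounts of 0.5 and 10, no filter, a filter of 50 in 3 libraries, TMM scaling, limma array weights and the replicate number as a block. Others were edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 Wald tests on recovered reads, a fit of only the groups compared, an estimated correlation for lists, and leaving out each library. Chosen after the data were seen were a correction of each library for a trend in transcript GC content and length (values for 18152 of the 18175 genes), the log2 rRNA share of each library as covariate, the share of tested genes at 0 as covariate, the receptor list without Vipr2, and the omission of the library with most genes at 0 in each Vipr2-/- group, nSVE library 3 and SVE library 3. The labels do not say whether replicate numbers pair the libraries. Over 19 pairs of the same number, correlations of residuals lay between -0.0813 and 0.209, 3 of them over 0.1. Of 14 libraries, 6 correlated best with their own number, so pairing is not excluded. The tests were also tested on simulated data, with 200 genes changed by 1.5-fold to 8-fold. All counts were drawn anew from each gene's mean over all libraries and its estimated spread. The excess of genes at 0 in Vipr2-/- libraries was not simulated.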

Results

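The suprachiasmatic nucleus (SCN), the hypothalamic seat of the mammalian circadian clock, was cut out by laser from brain sections of mice. Its total RNA was sequenced in 14 libraries. Wild-type mice were compared with Vipr2-/- mice, which lack VPAC2, the receptor through which the peptide VIP couples SCN neurons to one another. Mice of each genotype either stayed in constant darkness without an exercise schedule (nSVE) or had a wheel for 6 h of every 24 h, a scheduled voluntary exercise (SVE) to which activity rhythms can entrain. The groups held 4 wild-type nSVE, 4 wild-type SVE, 3 Vipr2-/- nSVE and 3 Vipr2-/- SVE libraries. Sampling was at circadian or schedule time 14, which under SVE was 2 h after the wheel became available. SVE lasted 35 to 40 days in wild type and 6 to 9 days in Vipr2-/- mice. Because the authors excluded wild-type mice that did not entrain and arrhythmic nSVE Vipr2-/- mice, those groups hold selected animals. For the wild-type SVE mice the series text also gives circadian time 24, against 14 in the other groups. By that text the exercise comparison in wild type is also one between circadian times. Per library, the deposited values corresponded to 17709080 to 48794679 reads and 15442 to 21906 genes with at least 1 read. Of the 18175 genes tested, 6.94% ± 1.66 (SD, n = 4) stood at 0 in wild-type nSVE libraries and 3.21% ± 1.54 (n = 4) in wild-type SVE. The share was 14.5% ± 5.32 (n = 3) in Vipr2-/- nSVE and 10.3% ± 6.17 (n = 3) in Vipr2-/- SVE. An rRNA-related gene, CT010467.1, took 15.03% ± 8.11 and 5.18% ± 5.21 of the reads in wild-type nSVE and SVE. In Vipr2-/- nSVE and SVE it took 11.5% ± 7.75 and 3.22% ± 0.518. No label says that the libraries of a group came from separate animals, so p-values measure the spread between these samples. Group values below are mean normalized read counts ± SD with n = 4 for wild-type and n = 3 for Vipr2-/- groups. Effects are limma log2 fold changes.

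The targeted gene itself, Vipr2 (ENSMUSG00000011171.11; GRCm38 chromosome 12, 116077726 to 116146261), showed the genotype in each library. Its transcript averaged 178.3 ± 37.3 in Vipr2-/- nSVE against 6656 ± 341 in wild-type nSVE, a log2 fold change of -5.23 ± 0.255 (SE, adjusted p = 1.55e-08). Under SVE the averages were 176 ± 77.9 and 8192 ± 1483, a change of -5.63 (adjusted p = 5.07e-09). Exercise did not move Vipr2 past the threshold in wild type (log2 fold change 0.28, adjusted p = 0.736) or in Vipr2-/- mice (-0.11, adjusted p = 0.883).

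What loss of VPAC2 does to the free-running SCN was asked by comparing the nSVE groups, from which arrhythmic Vipr2-/- mice had been excluded. Peptides of the nucleus itself were among the genes that differed. Avp, which encodes the vasopressin of SCN output neurons, averaged 6525 ± 2411 in Vipr2-/- against 13550 ± 949.8 in wild type (log2 fold change -1.13 ± 0.231 SE, adjusted p = 0.0341). Vip, the ligand of the missing receptor, averaged 4464 ± 637 against 8487 ± 1330 (-0.92, adjusted p = 0.0191). Sst, the somatostatin gene, averaged 3095 ± 1184 against 6670 ± 1141 (-1.17, adjusted p = 0.0191). Prok2, a secreted output signal, averaged 3.39 ± 5.87 against 70.5 ± 27.9 (-4.92, adjusted p = 0.0361). Penk, which encodes enkephalin, went the other way, with 5925 ± 1313 against 2936 ± 368 (1.00, adjusted p = 0.00447). Of 13 SCN neuropeptide genes tested, 4 were lower and 1 higher over all genes, and 4 lower and 3 higher adjusted over the list alone. The list as a unit did not pass (adjusted p = 0.407). Among clock genes Per2 averaged 2140 ± 579 against 4148 ± 458 without passing (-0.98, adjusted p = 0.105). Neither Nr1d1 (0.72, adjusted p = 0.0799), Dbp (0.89, adjusted p = 0.114), Arntl, the Bmal1 gene (-0.54, adjusted p = 0.265), Per1 (0.13, adjusted p = 0.876) nor Fos (-0.71, adjusted p = 0.655) passed. The Avp call ended without any 1 of the wild-type libraries 1 to 4 or Vipr2-/- library 2 (highest adjusted p = 0.11). The Sst call ended without wild-type library 1, 3 or 4 (0.0757) and the Vip call without wild-type library 2 or 3 (0.0757). Prok2 lost its call in 6 of 7 such omissions (0.118), whereas Penk passed in all 7 (highest 0.0217). The Prok2 average in Vipr2-/- lay near 0, and a transcript lost whole from a library also reads 0.

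The nSVE genotype comparison called 111 genes, the peptides included, 23 higher and 88 lower in Vipr2-/- mice. In all 111 the libraries of the groups did not overlap. Mobp, a myelin gene, averaged 3215 ± 32.2 against 10380 ± 1716 (-1.68, adjusted p = 2.1e-05), though the oligodendrocyte markers as a set did not pass (6 of 10 lower, adjusted p = 0.407). Igfbp5 averaged 19980 ± 383 against 32290 ± 1699 (-0.69, adjusted p = 0.00567). Rasd1, a light-responsive G protein, averaged 3825 ± 580 against 9282 ± 2289 (-1.26, adjusted p = 0.0236) and Kcnc2, a channel of fast-firing neurons, 1973 ± 298 against 3268 ± 41.1 (-0.74, adjusted p = 0.0149). Serpinf1 averaged 405 ± 124 against 55.8 ± 5.38 (2.79, adjusted p = 0.00762). Gpc3 averaged 3142 ± 362 against 1274 ± 112 (1.30, adjusted p = 0.000472) and Ddc, of dopamine synthesis, 1123 ± 281 against 546 ± 117 (1.04, adjusted p = 0.0349). Rtp1, Tmem181b-ps, Tmem254b, Tmem254c, Pisd-ps1 and Chodl were also among the largest rises (log2 fold changes of 5.81, 3.27, 2.28, 2.32, 1.30 and 1.27). Tmem181b-ps, Tmem254b, Tmem254c and Pisd-ps1 have close relatives with which they can share reads. Aldoc, of astrocyte glycolysis, averaged 52610 ± 11190 against 30610 ± 1955 (0.76, adjusted p = 0.0249). The 10 largest falls were of genes with no read in any Vipr2-/- nSVE library, and 32 of the called genes had a group at 0. With 3 reads over the group as the floor, Atp8b5 was at least 124-fold and Ctla2a at least 103-fold lower. Kdr, the VEGF receptor of endothelium, was at least 74.3-fold lower. Tnfrsf12a, Psmc3ip, Myo5b, Lmo7, Smc2, Carnmt1 and Adgb were at least 49.3-fold to 61.6-fold lower. This floor covers counting error only. A transcript lost whole from a library also reads 0, so these folds do not bound its expression. The Vipr2-/- nSVE group had the largest mean share of genes at 0, though its libraries 1 and 2 had less than Vipr2-/- SVE library 3. Of 8 endothelial markers, Kdr included, 7 were lower (median log2 fold change -0.53, camera adjusted p = 0.0625, and 0.209 with an estimated correlation). Non-overlapping genes numbered 2029, or 11.2% of those tested against 5.71% by chance. In all, 2605 genes had an unadjusted p under 0.05 against 909 by chance. Leaving out 1 wild-type library gave 56, 51, 36 and 57 genes (libraries 1 to 4), and leaving out Vipr2-/- library 1 or 2 gave 269 or 251. The count was 518 with DESeq2, 53 with the nSVE libraries alone and 213 after correction for GC content and transcript length. It was 16 with the share of genes at 0 as covariate and 232 without the sparsest library of each Vipr2-/- group. Of 32 named calls, 12 passed in each of the 7 omissions, Mobp, Igfbp5, Gpc3, Serpinf1 and Kdr among them. Adgb and Lmo7 lost their calls in all 7, Ddc, Chodl and Pisd-ps1 in 6, and Aldoc in 5 (highest adjusted p 0.0852 for Aldoc and 0.0872 for Ddc). Rasd1, Rtp1, Psmc3ip and Smc2 lost theirs in 4, Ctla2a and Tnfrsf12a in 3, and Kcnc2 and Myo5b in 1. Without wild-type library 3 adjusted p rose to 0.0568 for Kcnc2 and 0.082 for Rasd1.

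Activity-dependent genes stood lower as a set in the free-running Vipr2-/- SCN. Of 20 immediate-early genes, which neurons switch on within minutes of firing, 19 were below wild type with a median log2 fold change of -1.10 (camera adjusted p = 0.00384, adjusted p = 0.626 with an estimated correlation). No member passed singly, over all genes or adjusted over the list alone. Egr1 averaged 772.1 ± 274 against 6085 ± 9713 (-1.69, adjusted p = 0.365), the wild-type spread exceeding its mean. Without wild-type nSVE library 2 or Vipr2-/- library 1 the set had adjusted p = 0.448 (median -0.62) or 0.0785, and 0.0706 with the share of genes at 0 as covariate. Heat shock protein genes were also lower, 12 of 15 members below 0 and 5 of them adjusted over the list alone (adjusted p = 0.00655, adjusted p = 0.528 with an estimated correlation). That call ended without Vipr2-/- library 1 (0.385). SCN receptors and G protein regulators passed as a set (adjusted p = 0.00655, adjusted p = 0.187 with an estimated correlation, and 0.0627 without Vipr2-/- library 1), but their list includes Vipr2, the deleted gene. Without Vipr2, 8 of 11 were lower and the set did not pass (adjusted p = 0.233, adjusted p = 0.424 with an estimated correlation). Rasd1 was called over all genes and 3 of the 11 adjusted over the list alone. Genes for GABA, the main transmitter of SCN neurons, stood higher, 14 of 19 above 0 with none passing singly or adjusted over the list alone (adjusted p = 0.00351, adjusted p = 0.209 with an estimated correlation). The GABA call ended with the share of genes at 0 as covariate (0.41). A set of 23 cAMP and CREB signalling genes had 15 above 0 (adjusted p = 0.0426, adjusted p = 0.209 with an estimated correlation), with 1 member higher adjusted over the list alone. Its median turned from 0.10 to -0.07 after the GC and length correction (adjusted p = 0.801). Its call ended in 9 more settings with the preset correlation, among them the omission of wild-type library 2 (0.087) or 3 (0.0848) or of Vipr2-/- library 1 (0.195), 2 (0.0746) or 3 (0.0806).

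Whether exercise narrows the gap between the genotypes was addressed by comparing them again under SVE, where the vasopressin and somatostatin deficits were still present. Avp averaged 4398 ± 1123 in Vipr2-/- against 13350 ± 2461 in wild type (-1.62 ± 0.231 SE, adjusted p = 0.00642) and Sst 2852 ± 559 against 8673 ± 900.9 (-1.62, adjusted p = 0.00329). Vgf, a secreted neuropeptide precursor, averaged 6833 ± 406 against 18370 ± 4095 (-1.40, adjusted p = 0.00164). Cck averaged 1597 ± 329 against 3057 ± 289 (-0.95, adjusted p = 0.0422) and Prokr2, the receptor of the Prok2 signal, 4301 ± 690.3 against 7193 ± 1101 (-0.74, adjusted p = 0.0302). Penk was again higher, 5686 ± 528 against 3098 ± 313 (0.88, adjusted p = 0.019). Vip averaged 3179 ± 776 against 5692 ± 796 and missed the threshold (-0.86, adjusted p = 0.0577). Of the clock genes, Nr1d1 was lower, 8593 ± 2881 against 16670 ± 1285 (-1.004, adjusted p = 0.0267). Tef, a clock-driven transcription factor, was higher, 10590 ± 1874 against 5906 ± 991 (0.84, adjusted p = 0.0422). Per2 (0.35, adjusted p = 0.536), Dbp (-0.17, adjusted p = 0.776), Per1 (-0.19, adjusted p = 0.812), Arntl (-0.31, adjusted p = 0.493), Prok2 (-1.64, adjusted p = 0.469) and Fos (-1.05, adjusted p = 0.486) did not pass. Sod3, an antioxidant enzyme, averaged 195 ± 38.3 against 838 ± 192 (-2.09, adjusted p = 0.00104). Tsc22d3, a glucocorticoid target, averaged 5166 ± 597 against 2662 ± 378 (0.96, adjusted p = 0.00642). The series text gives circadian time 24 for the wild-type and 14 for the Vipr2-/- SVE mice. By that text, genotype and circadian time are not separated in this comparison. Avp passed in 6 of 7 single-library omissions (0.0736 without Vipr2-/- library 3) and Tsc22d3 in 6 (0.0589 without Vipr2-/- library 1). Sst, Vgf and Sod3 passed in all 7. Nr1d1 and Cck lost their calls in 6 omissions each (highest 0.201 and 0.27). Penk, Tef and Prokr2 lost theirs in 5 each (0.161, 0.267 and 0.234).

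**Figure D1:**
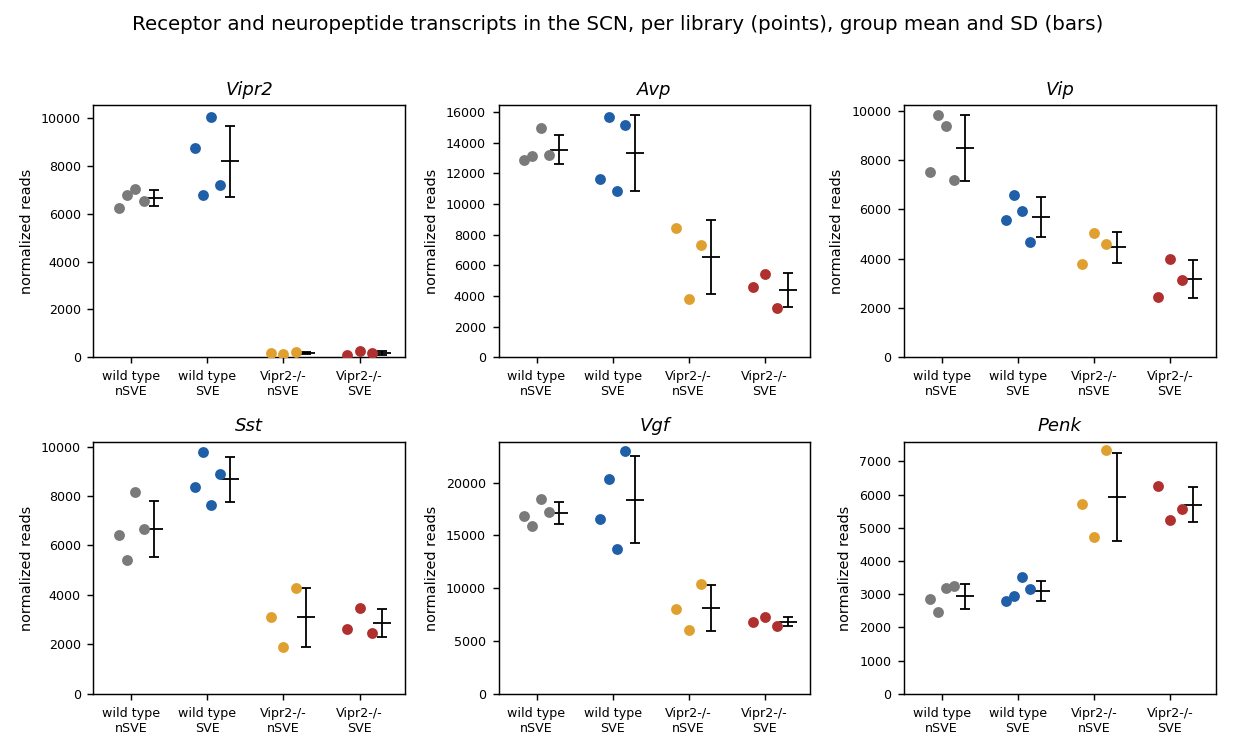
Normalized read counts of Vipr2, Avp, Vip, Sst, Vgf and Penk per library (points) in the 4 groups, with group mean ± SD. Avp averaged 13550 and 13350 in wild-type nSVE and SVE against 6525 and 4398 in Vipr2-/- nSVE and SVE, and Penk stood higher in Vipr2-/- libraries under both conditions.

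In all, the SVE genotype comparison called 32 genes, 9 higher and 23 lower in Vipr2-/- mice. The largest falls after Vipr2 included Tnni1 (2.55 ± 4.42 against 66.4 ± 28.7, log2 fold change -4.92), Creb3l1 (304 ± 119 against 1397 ± 719, -2.12), Wdfy1 (667 ± 146 against 2143 ± 252, -1.70) and Sertm1 (-1.52). Mobp was lower at 3516 ± 350.3 against 6471 ± 1026 (-0.87, adjusted p = 0.0162), while 6 of 10 oligodendrocyte markers were above 0, 3 higher and 1 lower adjusted over the list alone (set adjusted p = 0.29). Tmem181b-ps (3.43), Tmem254b (2.12), Tmem254c (2.11), Pisd-ps1 (1.38) and Vopp1 (0.82) were among the rises. Single-library omissions ended the calls of Tnni1, Wdfy1, Pisd-ps1 and Vopp1 in 6 of 7, of Sertm1 and Mobp in 4 and of Creb3l1 in 3 (highest adjusted p 0.234). The 3 other rises passed in all 7. With the 111 genes of the nSVE comparison 19 were shared, 6 higher and 12 lower in both, the deleted Vipr2 among the latter. Independent calls would share 0.0114 and 0.111 by chance, but both comparisons used the same spread estimate per gene. The other shared gene, Tmem51, was higher in Vipr2-/- mice under nSVE (0.73, adjusted p = 0.0426) and lower under SVE (-0.87, adjusted p = 0.0302). Each of its calls was lost in 6 of 7 omissions. Non-overlapping genes numbered 2569, or 14.1% against 5.71% by chance. Of all tested, 2730 genes had an unadjusted p under 0.05. Leaving out a single wild-type SVE library gave 15, 13, 14 and 18 genes (libraries 1 to 4). Leaving out Vipr2-/- SVE library 1, 2 or 3 gave 12, 1100 or 10. DESeq2 called 484, the SVE libraries alone 13, the GC and length correction 15 and the covariate for genes at 0 gave 6.

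Immediate-early genes were lower as a set under SVE as well. All 20 immediate-early genes were below wild type (median -1.09, camera adjusted p = 0.00155, adjusted p = 0.632 with an estimated correlation), none called over all genes and 2 adjusted over the list alone. Receptors and G protein regulators other than Vipr2 were lower in 10 of 11, with Prokr2 called and 4 adjusted over the list alone (adjusted p = 0.0425, adjusted p = 0.275 with an estimated correlation). That call ended without wild-type library 3 (0.0843) or Vipr2-/- library 1 (0.122, median from -0.59 to -0.35) or 2 (0.187). With Vipr2 in the list adjusted p was 0.00155 and 0.0627. RNA-binding proteins including the cold-inducible Cirbp and Rbm3 were higher in 7 of 7 (adjusted p = 0.00155, adjusted p = 0.275 with an estimated correlation). No single member passed, over all genes or adjusted over the list alone. Cirbp averaged 1868 ± 119 against 1375 ± 181 (0.45, adjusted p = 0.321) and Rbm3 461.6 ± 86.2 against 329.9 ± 79.2 (0.50, adjusted p = 0.397). Glucocorticoid-responsive genes were higher in 8 of 13, with Tsc22d3 called and 4 adjusted over the list alone (adjusted p = 0.00711, adjusted p = 0.275 with an estimated correlation). That call was lost without Vipr2-/- library 2 (0.181). GABA genes were higher in 13 of 19, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00711, adjusted p = 0.275 with an estimated correlation). Gad2 averaged 17410 ± 2056 against 14100 ± 1455 (0.30, adjusted p = 0.224). The GABA call was lost without Vipr2-/- library 3 (0.0632, median from 0.30 to 0.17) and with the covariate for genes at 0 (0.385). Without wild-type library 2 it passed with a median of 0.17. After correction for GC content and length the set's median turned to -0.13 (adjusted p = 0.57). Astrocyte markers were higher in 8 of 10, 4 adjusted over the list alone and none over all genes (adjusted p = 0.00251, adjusted p = 0.275 with an estimated correlation, and 0.131 with the covariate for genes at 0).

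Averaged over both conditions, the genotype comparison called 5 of 13 SCN neuropeptide genes lower and 1 higher, though the list did not pass (adjusted p = 0.111). Sst (-1.39 ± 0.151 SE, adjusted p = 0.000158), Avp (-1.37, adjusted p = 0.000359) and Vip (-0.89, adjusted p = 0.00129) were among those lower, and Penk was higher (0.94, adjusted p = 0.000158). These 4 passed whichever of the 14 libraries was left out. The receptors Prokr2 (-0.58, adjusted p = 0.00548) and Gpr176 (-0.54, adjusted p = 0.0066) and the G protein Rasd1 (-0.98, adjusted p = 0.0112) were lower, also in each omission. Higher in Vipr2-/- mice were Slc18a2, the vesicular monoamine transporter (1.56, adjusted p = 0.0346), and Drd5, a dopamine receptor (1.00, adjusted p = 0.0492). The list of dopamine, serotonin and orexin receptors did not pass (adjusted p = 0.285). Also higher, and both chosen after their values were seen, were Maob (0.97, adjusted p = 0.0279) and Ddc (0.93, adjusted p = 0.00566). Slc18a2, Drd5 and Maob lost their calls in 8, 11 and 7 of 14 omissions (highest adjusted p 0.0906, 0.123 and 0.0822), and Ddc in none. Gabra3, a GABA receptor subunit, rose by 0.50 (adjusted p = 0.0192; 0.0513 without Vipr2-/- SVE library 3, and above 0.05 without wild-type nSVE library 3). Tef rose by 0.74 (adjusted p = 0.0033), Tsc22d3 by 0.56 (adjusted p = 0.01) and Klhl1 by 1.24 (adjusted p = 0.0312, lost in 7 of 14 omissions). Serpinf1 rose by 1.92 (adjusted p = 0.00571). Mobp (-1.27, adjusted p = 5.02e-06) and Igfbp5 (-0.48, adjusted p = 0.00343) were lower in every omission, whereas the oligodendrocyte list did not pass (5 of 10 lower, adjusted p = 0.808). Also lower in every omission were the sparsely read Psmc3ip, Arhgap10, Atp8b5, Myo5b and Abca9 (fitted log2 fold changes -5.29, -5.17, -5.03, -4.91 and -4.88). Vipr2-/- SVE library 2 had the smallest share of genes at 0 of its genotype (3.99%). Its 36.54 of Arhgap10, 87.53 of Atp8b5 and 43.34 of Abca9 lay within the wild-type ranges, its 15.3 of Myo5b below. Passing in every omission thus does not show these genes low in each Vipr2-/- library. Nr4a3 (-1.36, adjusted p = 0.0392), Hspa1a (-1.15, adjusted p = 0.0462, its reads shared with a near-identical copy), Dnajb1 (-0.58, adjusted p = 0.0348) passed here, as did Grin2c (-0.55, adjusted p = 0.0333), Unc13a (-0.43, adjusted p = 0.0338), Aldoc (0.45, adjusted p = 0.0494) and mt-Atp6 (0.65, adjusted p = 0.0435). For each of these 7 genes, 7 to 12 of 14 omissions ended the call.

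The averaged comparison called 215 genes, 66 higher and 149 lower, of which 35 had a group at 0. Single omissions moved this count to 123, 128, 93 and 136 (wild-type nSVE libraries 1 to 4), and 101, 99 and 111 (wild-type SVE libraries 1, 2 and 4). They moved it to 428 (Vipr2-/- nSVE library 3) and 84, 1007 and 113 (Vipr2-/- SVE libraries 1 to 3). It was 131 with edgeR, 825 with DESeq2, 139 without a filter, 488 after the GC and length correction and 12 with the covariate for genes at 0. Immediate-early genes were lower in 20 of 20, with Nr4a3 called and 4 adjusted over the list alone (camera adjusted p = 3.42e-05, adjusted p = 0.425 with an estimated correlation). The receptor and G protein set without Vipr2 had 9 of 11 lower, 3 called and 3 adjusted over the list alone (adjusted p = 0.023, adjusted p = 0.216 with an estimated correlation). That call ended without Vipr2-/- nSVE library 1 (0.056) or Vipr2-/- SVE library 1 (0.0559) or 2 (0.0974). With the deleted gene in the list adjusted p was 0.000288 and 0.045. GABA genes were higher in 13 of 19, with Gabra3 called and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.000132, adjusted p = 0.185 with an estimated correlation). The GABA call did not hold after the GC and length correction (0.358, median from 0.20 to -0.01) or with the covariate for genes at 0 (0.203). Astrocyte markers were higher in 7 of 10, with Aldoc called and 2 adjusted over the list alone (adjusted p = 0.00384, adjusted p = 0.242 with an estimated correlation). With the covariate for genes at 0 their median went from 0.15 to 0.04 (adjusted p = 0.429). The RNA-binding set was higher in 7 of 7, no member called, even adjusted over the list alone (adjusted p = 0.0114, adjusted p = 0.33 with an estimated correlation). Its call was lost without Vipr2-/- nSVE library 1 (0.092, median from 0.20 to 0.11) or Vipr2-/- SVE library 3 (0.0555, median 0.13). It was also lost with the covariate for genes at 0 (0.136). Heat shock genes were lower in 12 of 15, with Hspa1a and Dnajb1 called and 6 adjusted over the list alone (adjusted p = 0.0133, adjusted p = 0.425 with an estimated correlation). Adjusted p was 0.0572, 0.126 and 0.196 without wild-type SVE library 1, Vipr2-/- nSVE library 1 and Vipr2-/- SVE library 2. Glucocorticoid-responsive genes were higher in 8 of 13, with Tsc22d3 called over all genes and adjusted over the list alone (adjusted p = 0.036, adjusted p = 0.389 with an estimated correlation). That call was lost without wild-type nSVE library 1 (0.0681), wild-type SVE library 1 (0.0617) or 3 (0.0783), Vipr2-/- nSVE library 3 (0.123) or Vipr2-/- SVE library 2 (0.17).

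The effect of the exercise schedule on an intact SCN was asked in wild-type mice, where clock genes changed most. Nr1d1, which encodes the clock repressor REV-ERB alpha (ENSMUSG00000020889.11; chromosome 11, 98767932 to 98775333), rose from 4325 ± 558 to 16670 ± 1285, 3.87-fold (log2 fold change 1.95 ± 0.16 SE, adjusted p = 3.44e-05). Rgs16, a regulator of G protein signalling that is rhythmic in the SCN, rose from 4481 ± 687 to 15100 ± 5362 (1.70, adjusted p = 0.000578). Per2 fell from 4148 ± 458 to 1682 ± 642 (-1.38, adjusted p = 0.0135) and Cry1 from 1290 ± 141 to 693 ± 82.3 (-0.90, adjusted p = 0.0136). Dbp, at 5710 ± 2355 against 3190 ± 198 (0.76, adjusted p = 0.112), Per1 (0.50, adjusted p = 0.512) and Arntl (-0.10, adjusted p = 0.952) did not pass. Of 24 clock genes, 1 rose and 2 fell over all genes and 4 rose and 4 fell adjusted over the list alone. The list as a unit did not pass (adjusted p = 0.331). Nr1d1 and Rgs16 passed in each of 8 single-library omissions (highest adjusted p 0.000411 and 0.00457). Per2 reached 0.0635 without nSVE library 1 and lost its call without SVE library 1 too. Cry1 reached 0.0521 without SVE library 1 and lost it without nSVE library 4. With the rRNA share of each library as covariate, Per2 (-1.39, adjusted p = 0.165) and Cry1 (-0.97, adjusted p = 0.165) no longer passed. The series text gives circadian time 24 for the SVE and 14 for the nSVE group, so the schedule and the time of sampling are not separated for these genes.

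**Figure D2:**
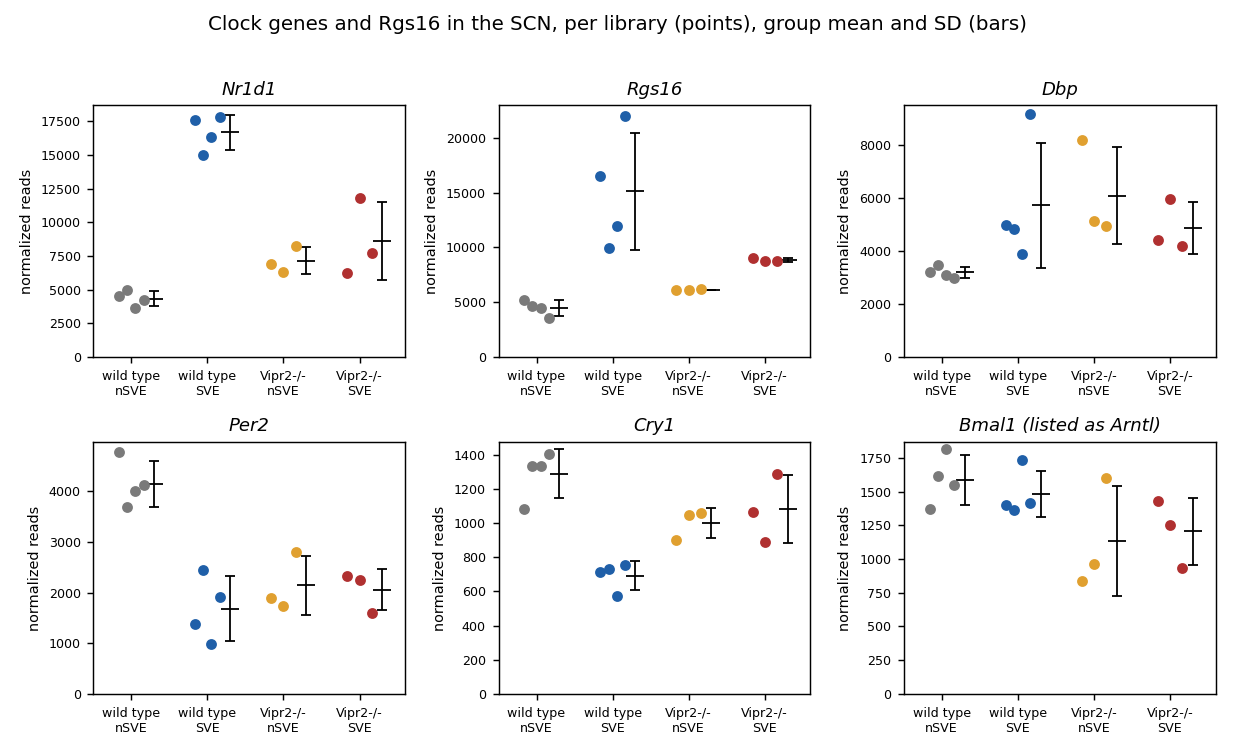
Normalized read counts of Nr1d1, Rgs16, Dbp, Per2, Cry1 and Bmal1 (Arntl) per library (points) in the 4 groups, with group mean ± SD. Nr1d1 rose from 4325 to 16670 with SVE in wild type and averaged 7148 and 8593 in Vipr2-/- nSVE and SVE.

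Single genes of neurons passed with SVE in wild type as well. The lists of neuropeptides (adjusted p = 0.198), immediate-early genes (0.198), ion channels (0.373) and synaptic vesicle genes (0.0714) did not. Npas4, an activity-dependent transcription factor, rose from 305 ± 114 to 940.6 ± 354 (1.63, adjusted p = 0.0302). The calcium channel genes Cacna1g and Cacna1d rose from 7034 ± 696 to 13100 ± 2199 (0.89, adjusted p = 0.0164) and from 2277 ± 279 to 3463 ± 364 (0.61, adjusted p = 0.0232). Among peptides, Nms, of a subset of SCN neurons, rose from 797 ± 45.6 to 1274 ± 159.5 (0.67, adjusted p = 0.0378) and Pcsk1n from 40490 ± 4090 to 74970 ± 12940 (0.88, adjusted p = 0.0217). Avp (-0.04, adjusted p = 0.99), Vip (-0.57, adjusted p = 0.0915), Prok2 (1.42, adjusted p = 0.624) and Fos (0.85, adjusted p = 0.683) did not pass. Transcription factors that specify the SCN were higher as a set in 6 of 7 members (camera adjusted p = 0.00339, adjusted p = 0.089 with an estimated correlation). Six3 was called (10510 ± 1095 to 15840 ± 1211, 0.59, adjusted p = 0.0283) and 4 passed adjusted over the list alone. Lhx1, at 3949 ± 470.1 against 2672 ± 391, was 1 of those 4 (0.57, adjusted p = 0.0613 over all genes). Mbd6 rose from 1571 ± 305 to 4988 ± 1195 (1.66, adjusted p = 0.00607). Nppc rose from 112 ± 52 to 563 ± 158 (2.39, adjusted p = 0.0156), Ankrd63 from 219 ± 78.6 to 856 ± 256 (1.98, adjusted p = 0.0135) and Vegfa from 828 ± 47.6 to 1282 ± 226 (0.62, adjusted p = 0.0448). Map4k1 had 92.6 ± 41.2 against no read in the nSVE group, at least 130-fold higher if only counting error is allowed for. Baiap2l2 (4.89), Rasl11b (2.44) and Tgfbr3l (1.73) were also among the largest rises. Sema3e (273 ± 29.1 against 606 ± 86.3, -1.14) and Tsc22d3 (2662 ± 378 against 4354 ± 591, -0.71, adjusted p = 0.0168) fell. Mbd6 passed in each of 8 single-library omissions. Ankrd63 and Nppc lost their calls in 2 (SVE library 1 in both, with nSVE library 1 for Ankrd63 at 0.0627 and SVE library 4 for Nppc at 0.0858). Calls were lost for Cacna1g in 3, Cacna1d in 5, Npas4 and Pcsk1n in 6, Six3 in 7, and Nms and Vegfa in 8 (highest adjusted p 0.151 and 0.204). They were lost for Tsc22d3 in 2, Map4k1 and Baiap2l2 in 7, and Rasl11b, Tgfbr3l and Sema3e in 8. Of 39 named calls in this comparison, 8 passed in each of the 8 omissions.

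Transcripts of ribosomal proteins and of nuclear-encoded respiratory proteins were lower after SVE in wild type. All 24 cytosolic ribosomal protein genes were below nSVE, with a median log2 fold change of -0.40 (camera adjusted p = 5.33e-17, adjusted p = 0.089 with an estimated correlation). Of these, 5 passed over all genes and 16 adjusted over the list alone. Rpl3 fell from 16360 ± 1072 to 9793 ± 1981 (-0.76, adjusted p = 0.0105). Rps14 (-1.04, adjusted p = 0.0401), Rpl11 (-0.66, adjusted p = 0.0238) and Rpl7 (-0.55, adjusted p = 0.0439) fell too, as did Rpl39 (-0.90) and the pseudogene Rpl9-ps7 (-1.04) outside the list. Ribosomal protein genes have many processed copies with which reads can be shared. Of 27 nuclear genes of oxidative phosphorylation 25 were below nSVE (median -0.30, adjusted p = 1.73e-05, adjusted p = 0.139 with an estimated correlation). Ndufa4 was the 1 member called, over all genes and adjusted over the list alone (3944 ± 249.7 to 2350 ± 273, -0.75, adjusted p = 0.0105). Of 13 mitochondrially encoded genes 7 were below nSVE (median -0.03, adjusted p = 0.373). Outside these lists, Atp5md and C1d fell by 1.23 and 1.12. These sets and the share of reads in CT010467.1 (15.03% in nSVE, 5.18% in SVE) moved in the same direction. Oligodendrocyte markers were lower in 9 of 10 (adjusted p = 2.42e-05, adjusted p = 0.182 with an estimated correlation). Mobp (10380 ± 1716 to 6471 ± 1026, -0.68, adjusted p = 0.0194) and Mal (1716 ± 123 to 1078 ± 58.4, -0.67, adjusted p = 0.0442) were called and 4 passed adjusted over the list alone. Astrocyte markers were lower in 8 of 10, none over all genes, 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.00711, adjusted p = 0.186 with an estimated correlation; 0.0549 without nSVE library 1, 0.0871 with the covariate for genes at 0). Red blood cell genes were lower in 5 of 5, with Hbb-bt (-1.45) and Hbb-bs (-1.13), near-identical in sequence, called over all genes and adjusted over the list alone (adjusted p = 0.00159, adjusted p = 0.346 with an estimated correlation). Glucocorticoid-responsive genes were lower in 12 of 13, with Tsc22d3 called and 2 adjusted over the list alone (adjusted p = 0.000251, adjusted p = 0.139 with an estimated correlation). Ndufa4 passed in each of 8 omissions and Rpl3 in 7 (0.0521 without SVE library 1). C1d passed in 6, Mobp in 3, Rpl11, Rpl39, Rpl9-ps7 and Hbb-bs in 2, Rps14, Atp5md and Hbb-bt in 1 and Rpl7 and Mal in none.

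In wild type 233 genes changed with SVE, 186 higher and 47 lower, 12 of them with a group at 0. Non-overlapping genes numbered 2665, or 14.7% against 2.86% by chance, and 231 of the 233 were among them. In all, 2270 genes had an unadjusted p under 0.05. Leaving out nSVE libraries 1 to 4 gave 36, 74, 89 and 58 genes. Leaving out SVE libraries 1 to 4 gave 29, 151, 73 and 38. DESeq2 called 727, the wild-type libraries alone 1201, limma with array weights 1693 and the GC and length correction 57. The covariate for genes at 0 gave 75, the fit without the sparsest library of each Vipr2-/- group 739, and the rRNA covariate left 3.

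Whether exercise acts on the SCN without VPAC2 signalling was asked in Vipr2-/- mice, where the clock genes that changed in wild type did not pass. Nr1d1 averaged 8593 ± 2881 with SVE against 7148 ± 1007 without (0.22, adjusted p = 0.604) and Per2 2053 ± 402 against 2140 ± 579 (-0.05, adjusted p = 0.961). Rgs16 averaged 8850 ± 156.7 against 6123 ± 36.7, higher in each SVE library, without passing (0.53, adjusted p = 0.304). Cry1 (0.10, adjusted p = 0.83), Dbp (-0.30, adjusted p = 0.607), Per1 (0.18, adjusted p = 0.824), Arntl (0.12, adjusted p = 0.825) and Fos (0.51, adjusted p = 0.772) did not pass. Nor did Avp (-0.52, adjusted p = 0.36), Vip (-0.51, adjusted p = 0.251) or Prok2, at 64.8 ± 33.3 against 3.39 ± 5.87 (4.70, adjusted p = 0.111). Kdr averaged 189 ± 49.1 with SVE against no read without it, at least 159-fold higher (adjusted p = 9.94e-05). Syk (123 ± 67.4), Perp (86.6 ± 68.5), Pde5a (79.5 ± 7) and Carnmt1 (69 ± 35.9) were likewise at 0 without SVE. Against the floor they were at least 104-fold, 73-fold, 67-fold and 58.2-fold higher. These folds, that of Kdr included, allow for counting error only and not for transcripts lost from a library. Banp rose from 829.4 ± 66.1 to 1626 ± 229.5 (0.96, adjusted p = 0.0124) and Ppp4r1 from 351 ± 82.2 to 938 ± 289 (1.39, adjusted p = 0.0476). Snrnp70, of the U1 splicing particle, rose from 1521 ± 56.5 to 2825 ± 96.2 (0.89, adjusted p = 0.0476), and Gjc1 (6.04) and Klhl4 (5.44) rose from near 0. The respiratory chain genes Ndufa4 and Ndufb11 fell, from 5066 ± 409 to 2650 ± 531 (-0.95, adjusted p = 0.0124) and from 3808 ± 289 to 2439 ± 299 (-0.65, adjusted p = 0.0476). Banp, Carnmt1, Kdr, Ndufa4 and Syk passed in each of 6 omissions. Snrnp70 lost its call in 4 (highest adjusted p 0.0987), Klhl4, Ndufb11 and Ppp4r1 in 3 each (0.121, 0.0987 and 0.13), and Gjc1, Pde5a and Perp without SVE library 1 (0.0912, 0.0637 and 0.0938).

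Ribosomal protein genes were lower after SVE in Vipr2-/- mice too, 23 of 24 below 0 with a median of -0.43 (camera adjusted p = 7.43e-12, adjusted p = 0.352 with an estimated correlation). Without nSVE library 3 the median was -0.20. None was called over all genes and 7 passed adjusted over the list alone. Rpl3 averaged 8881 ± 1156 against 13300 ± 585 (-0.59, adjusted p = 0.13). Of the oxidative phosphorylation genes 23 of 27 were lower, with Ndufa4 called and 2 adjusted over the list alone (adjusted p = 0.000564, adjusted p = 0.583 with an estimated correlation). That call ended without nSVE library 3 (0.0719, median from -0.18 to -0.09) or SVE library 2 (0.0814, median -0.125). It also ended without the sparsest library of each Vipr2-/- group (0.0704, median -0.08) and with the covariate for genes at 0 (0.0536). Red blood cell genes were lower in 4 of 5, none over all genes and 4 adjusted over the list alone (adjusted p = 0.00766, adjusted p = 0.623 with an estimated correlation). It ended without nSVE library 1 (0.167) or SVE library 3 (0.153, median from -0.99 to -0.59), and without the sparsest library of each Vipr2-/- group (0.26, median -0.49). It also ended with array weights (0.053) and with the rRNA share as covariate (0.0674). The share of reads in CT010467.1 was 11.5% without and 3.22% with SVE. The comparison called 21 genes, 18 higher and 3 lower, and 12 of them had no read in 1 group. Leaving out nSVE library 1 or 2 gave 177 or 112 genes, and SVE library 1 or 2 gave 6 or 72. DESeq2 called 394, edgeR 6, the Vipr2-/- libraries alone 0 by limma, limma with array weights 4. A pseudocount of 10 gave 5, no filter 6, a stricter filter 6. The GC and length correction 32, the rRNA covariate 3, the covariate for genes at 0 gave 8, and the fit without the sparsest library of each Vipr2-/- group 39. Non-overlapping genes numbered 1815, or 9.99% against 10% by chance. In all, 2516 genes had an unadjusted p under 0.05. Of the 233 genes of the wild-type comparison and these 21, Snrnp70, higher in both, and Ndufa4, lower in both, were shared. Independent calls would share 0.184 and 0.00776 by chance, but here too the spread estimate per gene was the same.

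**Figure D3:**
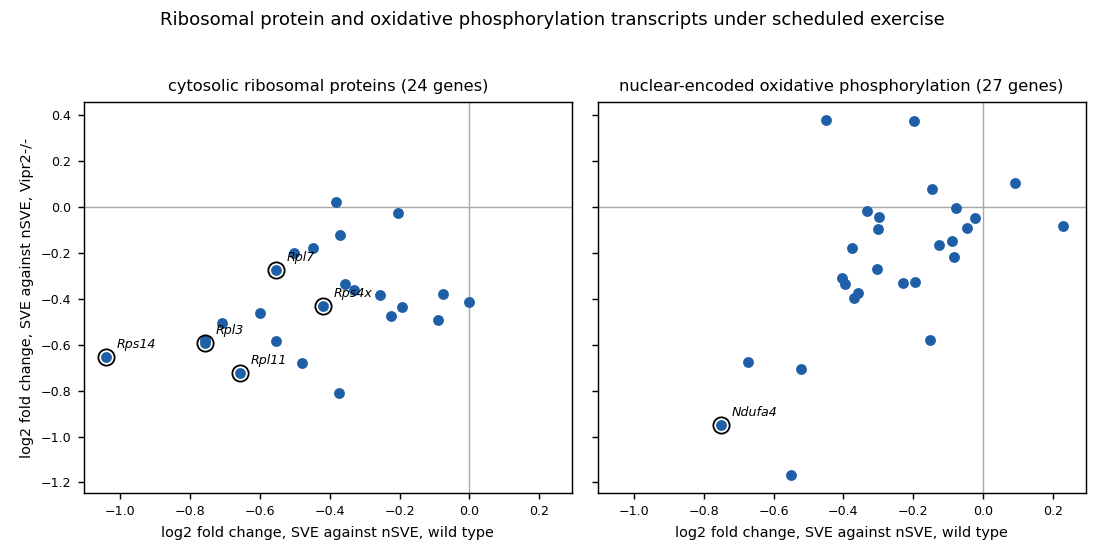
Log2 fold change with SVE in Vipr2-/- mice (vertical) against that in wild type (horizontal) for 24 cytosolic ribosomal protein and 27 oxidative phosphorylation genes (points), black rings marking genes that passed in either genotype. All 24 ribosomal protein genes lie below 0 in wild type and 23 in Vipr2-/- mice.

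The question of whether VPAC2 is needed for a response to exercise is put by the interaction, the SVE effect in Vipr2-/- minus that in wild type. Among clock genes Nr1d1 passed. Its change in Vipr2-/- mice (0.22) was below that in wild type (1.95), a difference of -1.73 ± 0.244 (SE, adjusted p = 0.0128). Tmem51, a membrane protein gene, went from 672.8 ± 33.7 to 1831 ± 93.6 in wild type and from 1132 ± 227 to 1008 ± 163 in Vipr2-/- mice (difference -1.61, adjusted p = 0.0117). Kdr went from 88.1 ± 27.1 to 153 ± 54 in wild type and from no read to 189 ± 49.1 in Vipr2-/- mice (fitted difference 6.75, adjusted p = 0.0117). Gm1848, named after its values were seen, went from 143 ± 21.9 to 150.5 ± 53.8 and from no read to 173 ± 43.2 (7.40, adjusted p = 0.00512). The corresponding differences for Rgs16 (-1.17, adjusted p = 0.293), Cry1 (0.99, adjusted p = 0.293), Per2 (1.33, adjusted p = 0.341), Carnmt1 (6.67, adjusted p = 0.0543) and Syk (6.35, adjusted p = 0.0742) did not pass. An effect that differs between genotypes was thus not shown for them. None of the 32 gene lists passed (lowest adjusted p = 0.129). The genotypes also differed in the length of SVE and, per the series text, in the circadian time of the SVE group. The count of 4 genes, 2 with a higher and 2 with a lower effect in Vipr2-/- mice, became 1 without wild-type SVE library 1, where Nr1d1 and Tmem51 had adjusted p = 0.0566. It became 36, 31 and 8 without Vipr2-/- nSVE library 1, 2 and 3 and 27 and 8 without Vipr2-/- SVE library 2 and 3. The Kdr call also ended without wild-type SVE library 2 (0.0583) or Vipr2-/- SVE library 1. DESeq2 called 175 genes, the fit without the sparsest library of each Vipr2-/- group 13 and the covariate for genes at 0 gave 7. With the replicate number as a block limma called 0, edgeR without it 6, and the 4 genes had adjusted p from 0.0761 to 0.0957. In all, 1877 genes had an unadjusted p under 0.05 against 909 by chance.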

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

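The tests of circadian time, of shared zeros and of other endothelial markers were chosen only after the result was seen. The corrections for rRNA share and for GC content and length were chosen after the data were seen, and the other tests here were set beforehand. In groups of 4, a library far from its neighbours was found for 15 of 254 gene and group combinations, where 12.7 arise by chance, so no single one of them calls for an explanation. In wild-type nSVE, library 1 stood apart with 33510 normalized reads of Aldoc (others 29260 to 29900), 1279 of Atp5md (1758 to 1827), 3004 of Gpr176 (3696 to 3789), 503.1 of Maob (293.5 to 305.1) and 2086 of Lhx1 (2841 to 2887). Library 2 of that group had 46600 of Pcsk1n (38150 to 38970), 4266 of Per1 (2799 to 2965) and 228.2 of Rasl11b (186.6 to 192.6), and library 3 had 30.53 of Psmc3ip (84.46 to 85.36) and 27.01 of Rtp1 (0 in the others). In wild-type SVE, library 3 had 1734 of Arntl (1367 to 1417), 963.1 of Chodl (652.6 to 693) and 990.8 of Mal (1099 to 1115), and library 4 had 82130 of Dlk1 (70350 to 71360) and 0 of Gm20658 (27.98 to 34.14). The effect of SVE differed between the genotypes, by the interaction test, for Nr1d1 (-1.729), Tmem51 (-1.606), Kdr (6.749) and Gm1848 (7.395).

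Regrouping the libraries showed which counts chance can give. No other split gave as many genes for genotype under nSVE (1 of 35 splits as large, 111 genes, highest other split 9) or under SVE (1 of 35, 32 and 1). The same held for SVE in wild type (1 of 35, 233 and 1) and averaged genotype (1 of 100, 215 and 81). These shares argue against chance without excluding it, since 1 of 35 is the lowest share that 35 splits can give. For SVE in Vipr2-/- mice the 10 splits are too few for a share under 0.05 (4 as large; 21 genes, highest other 50), and likewise for lists (5 as large; 3 lists, highest other 5). For the interaction the splits do not argue against chance (27 of 100 as large, 4 genes, highest other 264). A split with 264 genes points to a structure of the samples, which was not examined. Such splits mix nSVE with SVE libraries within each genotype, so real effects can enter them too. Nor do the splits argue against chance for the counts of lists. As large were 7 of 35 (5 lists, highest other 8) for genotype under nSVE and 9 of 35 (6 and 11) under SVE. For SVE in wild type 10 of 35 (7 and 11) were as large, and for averaged genotype 7 of 100 (7 and 9). For the interaction it was 100 of 100 (0 and 9).

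In wild-type SVE libraries Nr1d1 and Rgs16 rose and Per2 and Cry1 fell. With the rRNA share as covariate 4 of these 4 kept at least 0.5 of their log2 fold change, which argues against that share as the whole cause. Even so, Per2 (-1.38 ± 0.234 to -1.39 ± 0.301 SE, adjusted p = 0.165) and Cry1 (-0.90 ± 0.153 to -0.97 ± 0.195, adjusted p = 0.165) stopped passing. Their errors grew, and the adjustment over all genes under the covariate also enters the adjusted p. After the GC and length correction 4 of 4 again kept it, and passed, which argues against those biases. If SVE mice were at circadian time 24, near the start of the subjective day, Nr1d1, Rgs16, Dbp and Prok2 would be higher and Per2, Cry1 and Arntl lower: 7 of 7 had that sign in wild type and 4 of 7 in Vipr2-/- mice. The test was chosen after the result was seen, however, so these signs cannot be taken as predicted. The 3 genes not called in wild type (Dbp, Prok2 and Arntl) alone give an exact binomial p of 0.125 (one-sided). That p takes the genes as independent, and Arntl counted with a change of only -0.10 ± 0.189 (SE). The count of signs therefore cannot decide. Another circadian phase and a direct effect of exercise could not be told apart, because wild-type SVE mice were sampled in 1 group at 1 time.

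Genes called between the genotypes might lie in foreign DNA around the targeted Vipr2 allele. Within 20 Mb of Vipr2 lay 2.8% of the called genes of the averaged comparison, 6 genes (Chga, D430020J02Rik, Dlk1, Gm20658, Mirg and Tmem121), against 1.13% of the tested genes (Fisher's exact p = 0.0347, two-sided), an excess of few genes. This argues against linkage as the source of most calls and leaves it open for these 6.

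In the 3 Vipr2-/- nSVE libraries 43 genes with reads elsewhere stood at 0 together, 5.11 times the 8.42 expected if genes of like level were equally prone to loss in each library. All 20 choices of 3 Vipr2-/- libraries exceeded their own expectation (3.02 to 46.9 times), so an excess does not set the nSVE libraries apart. Genes that differ in this and were lost in each library apart, at its own rate, would fall on any 3 of the 6 Vipr2-/- libraries by those rates alone. Of 130 genes at 0 in exactly 3 of the 6, with a wild-type mean of at least 50, 9 were at 0 in the 3 nSVE libraries against 8.85 expected. This ratio of 1.02 (binomial p = 0.862) shows no excess for the nSVE condition, though the rates fit other choices of 3 less well (4 of 20 with p under 0.05). It does not decide for a single gene. For Kdr, a smaller share of endothelial cells would lower other markers alike. The other 7 had a median log2 fold change of 0.0802 (SE over the markers 0.316) with SVE, 5 of them above 0. Against wild type under nSVE the median was -0.424 (SE over the markers 0.248), 6 of them below 0. Each SE is that of a mean over the 7 markers and does not measure the spread between libraries. Both are far from the fall of Kdr (at least 74.3-fold if only counting error is allowed for). This argues against a smaller share as the whole cause and leaves a part of it open. What keeps Kdr and Gm1848 at 0 in these libraries and well above in the 11 others stays open.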

How the results depend on the processing

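Chosen only after the data were seen were the GC and length correction, the rRNA and zero-share covariates, the omission of the 2 sparsest libraries and the receptor list without Vipr2; the other alternatives were planned. The cause of a change in a count was not tested, except that leaving out libraries or fitting only 2 groups leaves fewer samples. Counts of called genes below are in the order genotype under nSVE (111 in the report), genotype under SVE (32), SVE in wild type (233), SVE in Vipr2-/- (21), interaction (4) and averaged genotype (215).

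The replicate block gave 49, 17, 137, 4, 0 and 69 genes, where the interaction's 0 compares with 6 by edgeR and 175 by DESeq2, and with 1877 genes at an unadjusted p under 0.05 in the unblocked fit. DESeq2 gave 518, 484, 727, 394, 175 and 825. A fit of only the groups compared gave 53, 13, 1201 and 0 for the first 4 comparisons. The covariate for genes at 0 gave 16, 6, 75, 8, 7 and 12. The GC and length correction gave 213, 15, 57, 32 and, averaged over conditions, 488. Without the 2 sparsest libraries the counts were 232 for genotype under nSVE, 739 and 39 for SVE in wild type and Vipr2-/-, and 13 for the interaction. With the rRNA covariate SVE called 3 genes in wild type and 3 in Vipr2-/-, and with array weights 1693 and 4. For SVE in Vipr2-/- a pseudocount of 10 gave 5 genes, no filter 6, the stricter filter 6 and edgeR 6. For the averaged genotype, no filter gave 139 and edgeR 131. TMM scaling and a pseudocount of 0.5 moved no count by over 1.5 times.

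Leaving out 1 library at a time gave 36 to 269 genes for genotype under nSVE, 10 to 1100 under SVE, 29 to 151 for SVE in wild type, 6 to 177 in Vipr2-/-, 1 to 36 for the interaction and 84 to 1007 averaged over conditions. The highest counts came without a Vipr2-/- library in the comparisons that hold one: nSVE library 1 (269, 177 and 36) and SVE library 2 (1100 and 1007).

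An estimated correlation between genes ended the list calls, with 0 lists in place of 5, 6, 7 and 3 for the first 4 comparisons and 1 in place of 7 averaged over conditions. That 1 was the receptor list, which holds the deleted gene. Without Vipr2 in it, 0 lists passed with an estimated correlation in the 3 genotype comparisons, and 3 in place of 5 with the preset one under nSVE, because the receptor and cAMP lists no longer passed. Array weights gave 10 lists for genotype under SVE and 3 for the interaction. The interaction had 5 lists without the 2 sparsest libraries and 5 after the GC and length correction, which also gave 11 lists averaged over conditions. The covariate for genes at 0 left 3 for genotype under nSVE. Single omissions gave 1 to 6 lists for genotype under nSVE (3 without wild-type library 2, 1 without Vipr2-/- library 1) and 0 to 5 for the interaction (1, 5 and 1 without wild-type SVE library 4, Vipr2-/- nSVE library 3 and Vipr2-/- SVE library 3). Among called lists, 3 medians changed sign, each after the GC and length correction: GABA under SVE (-0.1253) and averaged over conditions (-0.006201), and cAMP and CREB signalling under nSVE (-0.0703). None of the 3 then passed.

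Of 4575 recomputed values of named genes, 3498 stayed on their side of the threshold, 1036 fell back from it, 41 moved past it and 0 reversed. Of the named calls, the covariate for genes at 0 ended 112 of 160 and the replicate block 75 of 160, and leaving out wild-type SVE library 1 ended 60 of 116. Nr1d1 and Rgs16 passed in wild type under each of 22 alternatives, with log2 fold changes from 1.68 to 2.02 and from 1.49 to 1.88, and Per2 and Cry1 under 19 of 22.

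Small effects were often missed at the depth and group sizes of these data. Of 50 genes changed by 2-fold in simulated data, limma found 44%, 44%, 38%, 48%, 12% and 68% in the 6 comparisons, and of 50 changed by 8-fold 72%, 82%, 90%, 70%, 76% and 86%, so an uncalled gene is not shown to be unchanged.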

Other observations

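All values here were chosen after they were seen, and no explanation was tested for them. Meg3, Miat and Snhg11, 3 long noncoding RNAs, rose with SVE in wild type. Meg3 averaged 90200 ± 15860 (SD, n = 4) against 41320 ± 10110 (n = 4; limma log2 fold change 1.14, adjusted p = 0.00607), Miat 4535 ± 894 against 1596 ± 436 (1.53, adjusted p = 0.00209) and Snhg11 30420 ± 8213 against 14320 ± 4863 (1.11, adjusted p = 0.0283, lost in 5 of 8 single-library omissions). In Vipr2-/- mice the changes were 0.79 for Meg3 (adjusted p = 0.155), 0.98 for Miat (adjusted p = 0.105) and 1.01 for Snhg11 (adjusted p = 0.164). Of 2 postsynaptic scaffold genes, Shank1 rose in wild type by 0.78 (adjusted p = 0.0105) and Shank2 by 0.51 (adjusted p = 0.0358, lost in 8 of 8 omissions), against -0.01 and 0.11 in Vipr2-/- mice, neither of which passed. None of these 5 was among the 4 genes whose effect of SVE differed between the genotypes. Nnat (-1.14, adjusted p = 0.00129), Dlk1 (-0.51, adjusted p = 0.0143) and Mirg (-1.10, adjusted p = 0.0192), each imprinted, were lower in Vipr2-/- mice averaged over conditions. No list of noncoding RNAs, scaffold genes or imprinted genes was tested. Dlk1 lost its call without Vipr2-/- SVE library 1 (0.0534) and Mirg in 3 of 14 omissions (highest adjusted p 0.0672), and both lie within 20 Mb of Vipr2.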
